A study of Mus musculus with 295 samples.

How the data were processed

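Adipose tissue RNA of 295 F2 mice was isolated on spin columns with DNase treatment, amplified and labelled by an automated aminoallyl protocol, and hybridised against a pool of equal parts of all samples, per the labels. Each deposited sample file gives 2 intensity columns, 1 per dye. Per the file headers they are Cy3 and Cy5 intensity, and the values were all above 0, with array medians from 0.0939 to 0.175 in Cy3 and from 0.101 to 0.194 in Cy5. Scanner, background correction and dye normalisation are not given in the sources used here. The authors' value table of the whole series was found to hold log10 ratios of Cy5 over Cy3, from the slope of its columns on the log10 ratio of the deposited intensities (median 0.994, median r 0.995). Its column medians ran from -0.0222 to 0.0267, with 0.00752 as the median. Its values lay between -2 and 2. Columns of 2 arrays that share a mouse number matched each other's sample file (r 0.990 and 0.984) and not their own (r -0.11 and -0.112). Of the other columns, 27 had an r under 0.9 with their sample file, the lowest 0.476, all of them numbered up to 212 and 24 of them arrays of outlying SD. Slopes of the other columns ran from 0.404 to 1.03. The direction of the value table is thus settled against the intensity columns, and its scale for most columns, while how the columns were centred, and which dye truly carried the mouse, stay unknown.

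Ratios were formed as log2 of Cy5 over Cy3 intensity and normalised within each array by loess (limma, span 0.3, 4 iterations). No normexp background correction with an offset was applied, although it had been planned for intensities, because the deposited intensities were all above 0 and far smaller than such an offset. Whether their background had been corrected is unknown. Blank values made up 0.442% of all values. Probes were named from the table of the platform's annotation: of 23574 probes, 13665 had 1 gene symbol, 48 had several and 9861 had none there, and only probes with 1 symbol were used. Symbols were updated through the Entrez identifier for 12662 probes with the RefSeq table of assembly GRCm38.p6, which served for names, chromosome membership and neighbourhood only, since the files name no genome build. From these, 148 probes with a value in under 90 percent of arrays were left out. For 1295 genes with several probes the probe of highest mean intensity was kept, which left 11562 genes. Among all probes, 240 were blank in over 10 percent of arrays. They were bright (median intensity percentile 99.5), and 62.0% of their values were blank in the first array batch against 1.57% in the second.

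The design gives 1 group, so no groups were compared. Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Named were the 15 genes of highest SD, the 10 highest and 10 lowest partial r with Lep and with the macrophage list among those past the threshold, the 12 clustered genes with the widest separation, up to 4 members per list, the sex chromosome transcripts, and Lep, Adipoq, Adgre1 and the parental strain alleles (H2-Ea, Nnt, Tlr4, Abcc6 and Pde6b). Adipoq has no probe named here. Genes with occupied classes, genes at shares near 3 to 1 and further list members were named after their values were seen. The sex chromosome index was to combine Xist with Ddx3y, Eif2s3y, Kdm5d and Uty. Only Eif2s3y and Kdm5d have a named probe, so the index was the negative mean of these 2. It was taken out as a continuous covariate in the tests of co-expression, association and linkage.

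The 27 lists were adipocyte, expansion, lipogenesis, cholesterol synthesis, fatty acid oxidation, respiratory chain, brown adipocyte, macrophage, MHC class II, T cell, B cell, extracellular matrix, endothelium, mesothelium, interferon response, cell cycle, circadian clock, immediate early, chaperones, red blood cell, skeletal muscle, epididymis and seminal vesicle, mammary epithelium, exocrine pancreas, liver, sex chromosome transcripts and parental strain alleles. Co-expression of a list was its mean pairwise r after taking out the index, against 10000 random lists of its size matched on intensity decile. Genes were tested against Lep and against the macrophage list with limma's lmFit and eBayes and Benjamini-Hochberg adjustment at 0.05. List means of z scores were tested with Pearson's r and Spearman's rho and 100000 two-sided permutations of the mice, so that 1e-05 is the smallest p they can give. Clustered genes were called from equal-variance normal mixtures of 2 classes (smaller share at least 0.1) or 3 evenly spaced classes, with a BIC gain of at least 10 and classes at least 3 SD and 1.5-fold apart. Linkage compared pairs of clustered autosomal genes under 20 Mb apart with pairs on different chromosomes, with 10000 permutations of the positions. Array batches were found as the break along mouse number in the first component of the pool channel, which held 60.4% of that channel's variance.

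The calls of genes associated with Lep, of clustered genes and of co-expressed lists were tested on simulated data over the 11562 genes. For genes associated with Lep, 16% of genes simulated at a partial r of 0.15 and 95% at 0.3 were recovered, and 0.0704% of unchanged genes were called. The simulated genes varied independently and 100 followed Lep at each r, whereas 5201 genes passed in the real data. The adjusted threshold is stricter where fewer genes pass, so none of these 3 rates carries over to the real data. For clustered genes, 100% of those with classes 3.6 SD apart and 4% of those 2.5 SD apart were recovered, with 0% of unclustered simulated genes called. In the real data 189 of 190 genes called with 3 classes had an outer class of under 10 percent of mice. The 0% is thus no rate of false calls in the real data. For co-expressed lists, a list simulated at r 0.1 was recovered with an adjusted p of 0.0026, and 0 of 25 other lists were called.

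Alternatives tried were the value table, centring of arrays on their median, a filter on dim or incomplete probes, the mean over a gene's probes, no index, each cluster of the index, a spline of mouse number with 5 degrees of freedom, the first principal component as a covariate, ranks, and leaving out arrays of outlying SD (28 arrays over 3 median absolute deviations from the median) or of uncertain number (3 arrays). Narrower percentiles, wider class separation, other distances and other thresholds were tried for single results. Added after seeing the data were no loess, array batch as a covariate, each array batch alone, the sign turned, occupied classes and shares near 3 to 1. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.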

Results

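Transcript levels were measured in adipose tissue of 295 F2 mice from an intercross of the inbred strains C57BL/6J and C3H/HeJ. The animals were of both sexes and had eaten a high-fat, cholesterol-containing diet. Per the labels, chow with 4% fat was replaced at 8 weeks of age by a Western diet with 42% fat and 0.15% cholesterol. That diet lasted 12 weeks, and the mice were fasted for 12 hours and sacrificed at 20 weeks of age. RNA of each mouse was hybridised on a 2-colour array together with a pool that the labels describe as RNA from all mice. Every value is thus the ratio of 1 mouse to that pool. All mice form 1 group, because the labels give neither sex, direction of the cross, genotype nor body weight for a mouse. The data therefore describe how transcripts differ and vary together between mice, and no groups of the study were compared. Each array was taken as 1 mouse, although 2 arrays carry the same mouse number in the labels. The number of arrays limits the precision of every value. The median array had a median intensity of 0.134 in either channel, in the arbitrary units of the files. The series belongs to work on the genetics of gene expression, which uses exactly this variation between F2 animals.

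The direction of the ratios given here opposes the labels, which put the mouse in the Cy3 channel and the pool in Cy5. In the files it was the Cy5 column that varied between arrays. For Eif2s3y, a gene of the Y chromosome, log2 Cy5 intensity spanned a range of 8.45 over arrays and log2 Cy3 intensity 1.17. The Cy5 column lay farther from the common profile in 293 arrays and the Cy3 column in 2. Every log2 ratio here is Cy5 over Cy3, read as mouse over pool. Of 43365 pairs of arrays, 302 had a correlation below -0.3 over all probes, with -0.48 as the lowest r and 0.129 as the median, so the correlations alone do not settle the direction of single arrays. Eif2s3y bears on it: its log2 ratio was at most -4.11 in 143 arrays and no array had one above 1.297, so none of these 143 can be turned against the rest. The other 152 arrays were not checked singly. Turning the sign of every ratio leaves SDs, correlations between genes and the number of clustered genes as they are. It exchanges upper and lower classes and was counted separately for markers of other tissues.

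Among the 15 genes with the highest SD between mice, Gpx5, Lcn5, Lcn9, Spag11a and Ces5a are epididymal transcripts, and Svs6 is made in the seminal vesicle. Cuzd1 had the highest SD at 3.23 on the log2 scale, with a 5th percentile of -5.76 and a 95th percentile of 4.44. Eif2s3y followed with an SD of 3.16. The others were Crisp3 (SD 2.81), the matrix metalloproteinase Mmp7 (SD 2.62), the estrogen sulfotransferase Sult1e1 (SD 2.59), the urothelial protein Upk3a (SD 2.49), C4bp (SD 2.42) and BC048679 (SD 2.37). In the first and second array batch, which are described with the Y-linked transcripts, SDs were 1.35 and 3.18 for Ces5a, 1.21 and 3.08 for Lcn5, 1.25 and 3.15 for Spag11a, 1.476 and 2.91 for Gpx5, and 1.35 and 2.93 for Lcn9. They were 1.43 and 3.09 for C4bp, 1.45 and 2.97 for BC048679, and 1.11 and 1.43 for Svs6, which had an SD of 2.30 over all mice. Ucp1, the uncoupling protein of brown adipocytes, had an SD of 2.42, a 5th percentile of -4.07 and a 95th percentile of 3.18. Across 11562 genes, 5097 spanned at least 2-fold between the 5th and the 95th percentile of mice. Lep, which encodes the adipocyte hormone leptin and is known to follow fat mass, had an SD of 0.46, and its probe was at the 48.0th percentile of intensity among probes. Of the genes whose alleles are known to differ between the parents, Pde6b had an SD of 0.93, H2-Ea of 0.75, Nnt of 0.47, Tlr4 of 0.29 and Abcc6 of 0.23. In the first and second array batch these SDs were 1.24 and 0.36 for Pde6b, 0.93 and 0.48 for H2-Ea, 0.50 and 0.37 for Nnt, 0.28 and 0.32 for Tlr4, and 0.30 and 0.097 for Abcc6. Between the 10th and the 90th percentile, 2760 genes spanned 2-fold.

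Y-linked transcripts divided the mice sharply. Eif2s3y and Kdm5d, the 2 measured members of the sex chromosome list, were high in 152 mice and low in 143, with the clusters of their joint index 9.75 SD apart. Median log2 ratios of Eif2s3y were 0.56 in mice with high Y-linked transcripts and -5.84 in mice with low Y-linked transcripts, and those of Kdm5d were 0.32 and -3.91. The arrays also fell into 2 batches by mouse number, seen as a break in the pool channel, with 157 arrays up to number 212 and 138 from number 213. Both clusters were spread over both batches, with 79 and 78 mice in the first and 73 and 65 in the second. Batch means lay over 1.5-fold apart for 264 genes. Among mice with high Y-linked transcripts, medians in the first and second batch were 0.86 and 0.0978 for Eif2s3y and 0.828 and -0.0966 for Kdm5d. Ratios to the pool were thus offset between batches for these 2 genes. Whether the pool itself differed between batches was not tested. The mice form separate clusters, so correlations over all mice have the index taken out, as was fixed before the data were examined. SDs, percentile spans, clustered genes and counts of mice with markers of other tissues have the index left in, unless stated. Values or counts within each cluster stand beside those of many gene lists and of the genes with the highest and lowest r.

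Genes of the same cell type or pathway varied together from mouse to mouse. The tightest lists were the 4 red blood cell genes, with a mean pairwise r of 0.675, and the 18 macrophage genes, with a mean r of 0.645. Secretory genes of epididymis and seminal vesicle (0.624), skeletal muscle genes (0.538), cell cycle genes (0.528), fatty acid oxidation genes (0.508) and brown adipocyte genes (0.485) came next. MHC class II (0.442), adipocyte (0.399), extracellular matrix (0.391), lipogenesis (0.390) and respiratory chain genes (0.362) varied together as well. The same held, at lower values, for B cell (0.307), endothelium (0.289), mesothelium (0.234), exocrine pancreas (0.232), interferon response (0.227), cholesterol synthesis (0.194), T cell (0.183), immediate early (0.182), chaperone (0.172), mammary epithelium (0.084) and liver genes (0.0815). In all, 23 of 26 lists passed an adjusted p of 0.05 against 10000 random lists matched on intensity, by a one-sided test. The 3 others were the expansion list of genes known to track fat mass (mean r 0.124, adjusted p 0.0979), the circadian clock (0.025, adjusted p 0.144) and 5 genes whose alleles are known to differ between the parental strains (-0.014, adjusted p 0.561). Among mice with high and low Y-linked transcripts, 21 and 23 lists passed. In that order mean r was -0.0183 (adjusted p 0.598) and 0.371 for exocrine pancreas, 0.595 and 0.265 for epididymis and seminal vesicle, 0.289 and 0.591 for brown adipocyte and 0.0712 (adjusted p 0.108) and 0.114 for liver genes. In the first array batch mammary epithelium (mean r 0.0392, adjusted p 0.124) and exocrine pancreas (0.147, adjusted p 0.0721) did not pass, and in the second liver (0.0627, adjusted p 0.104) did not.

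Transcripts of adipocyte growth and of the vasculature rose with Lep in both clusters or in the whole set of mice. The paternally expressed gene Mest, a known marker of fat expansion, had a partial r of 0.469 with Lep, with 0.521 among mice with high Y-linked transcripts and 0.413 among mice with low Y-linked transcripts. Sncg (0.35) and Sfrp5 (0.345) rose as well, whereas the cyclin Ccnd1 fell (-0.237). Within the clusters with high and low Y-linked transcripts r was 0.52 and 0.267 for Sncg, 0.119 and 0.402 for Sfrp5, and -0.335 and -0.0382 for Ccnd1. Of 11 endothelial genes 7 rose and none fell, led by Cdh5 (0.464), the junction protein Esam (0.432) and the receptors Tie1 (0.419) and Flt1 (0.397). Within the clusters 9 and 3 of them rose, and Flt1 had r of 0.586 and 0.0594. The 10 genes with the highest partial r with Lep were LIMCH1 (0.604), the heme transporter Slc48a1 (0.591), Rbms1 (0.586), the autophagy protein Wipi1 (0.586), Crtac1 (0.581), the phosphodiesterase Pde2a (0.576), Reep5 (0.574), galectin-1 (Lgals1, 0.549), Trappc4 (0.543) and Tspan17 (0.541). The lowest were the heterochromatin protein Cbx1 (-0.531), Nufip1 (-0.497), Sobp (-0.472), Marchf9 (-0.460), the histone deacetylase Hdac2 (-0.458), Rerg (-0.454), Gem (-0.450), Abtb2 (-0.447), Gemin8 (-0.446) and Lrfn4 (-0.444). All 20 of these genes kept their sign within each cluster and each array batch. The 10 highest had r from 0.438 to 0.619 among mice with high Y-linked transcripts and from 0.447 to 0.65 among mice with low Y-linked transcripts, and the 10 lowest from -0.521 to -0.198 and from -0.529 to -0.371. By limma with the index as covariate, 5201 genes passed an adjusted p of 0.05, of which 2597 rose and 2604 fell with Lep, against at most 11 in 100 permutations of the mice. In the first and second array batch alone 3429 and 4104 genes passed.

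Fat storage and energy genes followed Lep in opposite directions in the clusters. Among mice with high Y-linked transcripts, 14 of the 15 lipogenesis genes rose with Lep and none fell, with r of 0.496 for the fatty acid synthase Fasn and 0.405 for Thrsp. Among mice with low Y-linked transcripts, 1 rose and 7 fell, with -0.216 for Fasn and -0.306 for Thrsp. Fatty acid oxidation genes divided in the same way, with 8 of 10 rising in the first cluster and 7 falling in the second. Adipocyte genes had 8 of 9 rising in the first and 3 falling in the second. Macrophage genes did the reverse: 12 of 18 fell with Lep where Y-linked transcripts were high, and 14 rose where they were low. Over all genes, 780 passed in both clusters with the same sign and 676 with opposite signs.

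Measured as list means, the macrophage list had r of -0.295 with Lep (rho -0.353) among mice with high Y-linked transcripts and 0.324 (rho 0.368) among mice with low Y-linked transcripts. The 2-sided permutation p were 0.00023 and 8e-05 for r, and 2e-05 and 3e-05 for rho. Benjamini-Hochberg adjustment over the 26 lists gave 0.000854 and 0.000693, and r was -0.321 and 0.333 without the 2 mice farthest from the median of Lep. In the first array batch r was -0.506 and 0.217 in these clusters, and in the second -0.224 and 0.532. The lipogenesis list had r of 0.479 (rho 0.494, both p 1e-05, the smallest the permutations can give) and -0.240 (p 0.00378, adjusted p 0.014, rho -0.239, p 0.00441), and r of 0.493 and -0.243 without 2 mice. Fatty acid oxidation gave 0.426 and -0.226, the respiratory chain 0.219 and -0.224, B cell genes -0.216 and 0.261, cell cycle genes -0.190 and 0.278, and epididymis and seminal vesicle genes -0.217 and 0.225, each past the threshold in both clusters. With low Y-linked transcripts, 0 mice had the epididymis and seminal vesicle list at least 4-fold above the median. Its r of 0.225 there may thus rest on low signal, which was not tested. The adipocyte list had r of 0.50 in the first cluster and did not pass in the second (-0.111, adjusted p 0.242). The expansion list rose with Lep in both (0.517 and 0.438). Endothelium reached 0.554 in the first and did not pass in the second (0.158, adjusted p 0.0922). The interaction of Lep with the index, a test chosen after these values were seen, passed for 15 of 26 lists. It did not pass for epididymis and seminal vesicle genes (adjusted p 0.615).

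**Figure D1:**
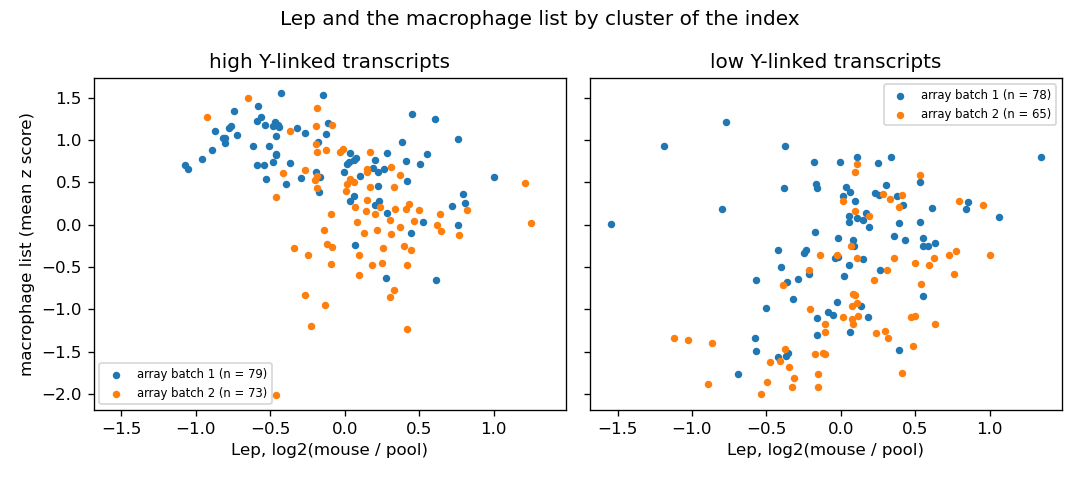
Each point is 1 mouse, with the log2 ratio of Lep (mouse over pool) on the horizontal axis and the mean z score of the macrophage list on the vertical axis, drawn in a panel for each cluster of Y-linked transcripts. The macrophage list falls with Lep among the 152 mice with high Y-linked transcripts (r = -0.295) and rises among the 143 with low Y-linked transcripts (r = 0.324).

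**Figure D2:**
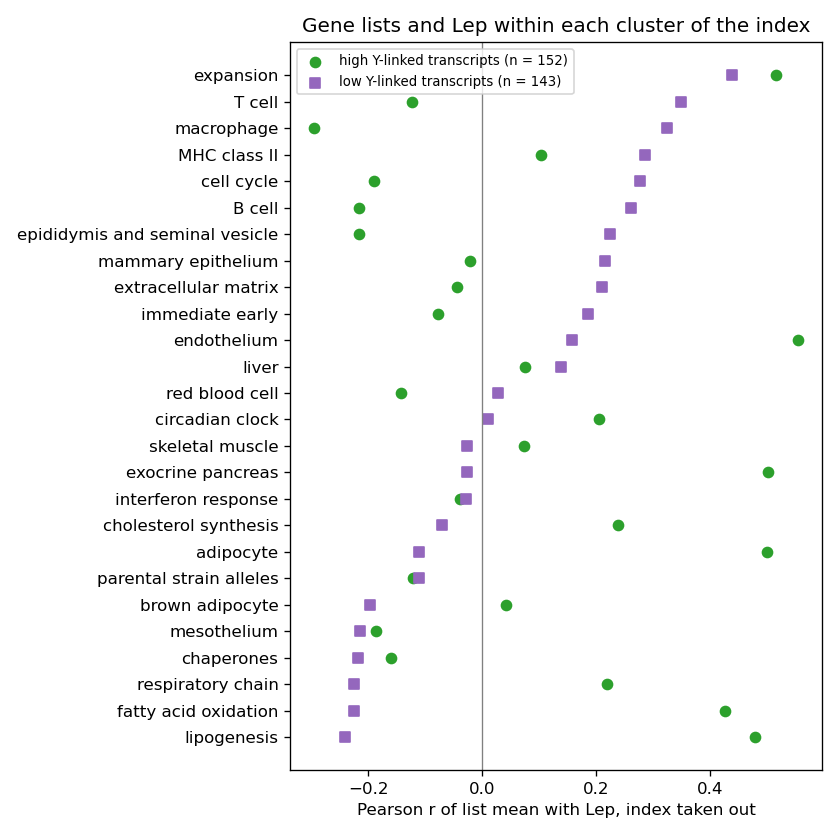
Points give the Pearson r (horizontal axis, no unit) between Lep and the mean of each fixed gene list (vertical axis) within each cluster of Y-linked transcripts. Lipogenesis lies at 0.479 and -0.240 and the macrophage list at -0.295 and 0.324, while the expansion list lies at 0.517 and 0.438.

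Over all mice, with the index taken out, 7 of 26 lists passed with Lep by r. Expansion had r of 0.441 (rho 0.435), endothelium 0.387 (rho 0.373), mammary epithelium 0.199 (rho 0.194), adipocyte 0.194 (rho 0.183), exocrine pancreas 0.178 (rho 0.347), chaperones -0.162 (rho -0.154) and the parental strain alleles -0.160 (rho -0.164). In that order the permutation p for r were 1e-05, 1e-05, 0.00066, 0.00089, 0.00247, 0.00541 and 0.00632, and adjusted p were 0.00013, 0.00013, 0.00572, 0.00578, 0.0128, 0.0234 and 0.0235. Of the adipocyte genes 6 rose, among them the aquaporin Aqp7 (0.334) and Pparg (0.289), and the same 6 was the count adjusted over the list alone. In the expansion list 4 rose and 1 fell, by either adjustment. Of the 11 mammary epithelium genes 3 rose and 8 did not pass, and of the 4 exocrine pancreas genes 1 rose and 3 did not pass. Of the 9 chaperones 3 fell, 1 rose and 5 did not pass. Of the 5 parental strain alleles 1 fell and 4 did not pass, and 0 passed when adjusted over the list alone. Several of these calls did not hold in both clusters. Mammary epithelium had r of -0.0219 (adjusted p 0.787) with high and 0.217 with low Y-linked transcripts, and exocrine pancreas 0.501 and -0.0267 (adjusted p 0.782). Chaperones had -0.160 (adjusted p 0.0834) and -0.218, and the parental strain alleles passed in neither, with -0.122 (adjusted p 0.193) and -0.112 (adjusted p 0.242). Without the 2 mice farthest from the median of Lep, r was 0.460, 0.387, 0.180, 0.198, 0.198, -0.163 and -0.176. Within the first and second array batches r was 0.450 and 0.557 for expansion, 0.402 and 0.354 for endothelium, 0.225 and 0.0543 for mammary epithelium, and 0.222 and 0.170 for adipocyte genes. It was 0.264 and 0.00376 for exocrine pancreas, -0.0852 and -0.374 for chaperones, and -0.18 and -0.22 for the parental strain alleles. Of these 7 lists, expansion and endothelium passed in both batches. Chaperones (adjusted p 0.416) and the parental strain alleles (0.0678) did not pass in the first, and mammary epithelium (0.593), adipocyte (0.0876) and exocrine pancreas genes (0.981) did not in the second. Fatty acid oxidation, which did not pass by r over all mice (r 0.0448), had 0.217 in the first batch and -0.207 in the second. No list mean was counted for the sex chromosome transcripts, which make up the index. Interferon response, mesothelium, circadian clock, T cell, skeletal muscle, red blood cell and liver genes did not pass by r over all mice, with r of -0.0967, -0.115, 0.13, 0.0919, -0.0165, -0.0799 and 0.0573. Of these, mesothelium passed in both clusters, with r of -0.187 (adjusted p 0.0377) with high and -0.215 (adjusted p 0.0203) with low Y-linked transcripts. Circadian clock genes passed in the first of these clusters alone (0.206, adjusted p 0.0238). T cell genes passed in the second alone (0.349, adjusted p 0.00026, against -0.124), and the others in neither. In the array batches T cell genes had r of 0.21 (adjusted p 0.0323) and -0.0564. MHC class II (0.13), extracellular matrix (0.0435), immediate early (-0.00319), cholesterol synthesis (0.0627) and brown adipocyte genes (-0.129) did not pass over all mice either. With low Y-linked transcripts, MHC class II (0.287), extracellular matrix (0.211), immediate early (0.186) and brown adipocyte genes (-0.197) passed. With high Y-linked transcripts, of these lists only cholesterol synthesis passed (0.238). MHC class II passed in both array batches (0.206 and 0.218). Extracellular matrix (-0.128 and 0.346) and brown adipocyte genes (-0.098 and -0.251) passed in the second alone. By rho, 3 of the lists that did not pass by r did so over all mice: circadian clock (rho 0.199, adjusted p 0.00377), fatty acid oxidation (0.153, adjusted p 0.0241) and mesothelium genes (-0.144, adjusted p 0.0369). With array batch as a further covariate, 10 lists passed, as MHC class II (r 0.207, adjusted p 0.00234), brown adipocyte (-0.180, adjusted p 0.00815) and mesothelium genes (-0.137, adjusted p 0.0499) passed as well.

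Mice with more macrophage transcripts had more matrix, antigen presentation and cell division transcripts, and fewer transcripts of mature fat cells and mitochondria. All 12 extracellular matrix genes rose with the macrophage list, with partial r of 0.723 for the collagenase Mmp2, 0.710 for Col5a2 and 0.666 for the inhibitor Timp1. All 4 MHC class II genes rose, including the transactivator Ciita (0.649) and H2-Aa (0.589), and 12 of 13 cell cycle genes rose, with Birc5 at 0.756 and Cdk1 at 0.687. Of the 8 respiratory chain genes 6 fell and none rose, led by Cox4i1 (-0.552) and Ndufv1 (-0.541). Fatty acid oxidation genes had 9 of 10 falling, with Ppara, the nuclear receptor that drives that pathway, at -0.683, and Cpt1a as the 1 that rose (0.385). Of 9 adipocyte genes 7 fell, including the insulin-responsive glucose transporter Slc2a4 (-0.701) and resistin (Retn, -0.619), and of 15 lipogenesis genes 12 fell, including Scd1 (-0.627). Endothelial genes fell as well, 8 of 11, with Kdr at -0.625 and Flt1 at -0.622. These counts were the same when adjusted over the list alone. Within the clusters with high and low Y-linked transcripts, 8 and 12 extracellular matrix, 3 and 4 MHC class II and 12 and 12 cell cycle genes rose. In that order 6 and 6 respiratory chain, 8 and 9 fatty acid oxidation, 8 and 5 adipocyte, 13 and 9 lipogenesis and 7 and 8 endothelial genes fell.

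The 10 genes closest to the macrophage list were Irf5 (partial r 0.965), the signalling adaptor Tyrobp (0.956), Arhgap25 (0.953), Blnk (0.947), Adgre1, which encodes the macrophage marker F4/80 (0.942), Capg (0.941), Slc15a3 (0.941), Myo1f (0.940), Evi2a (0.933) and Tmem106a (0.933). Each gene was set against the list without itself, and r of these 10 ran from 0.897 to 0.952 among mice with high Y-linked transcripts and from 0.945 to 0.973 among mice with low Y-linked transcripts. At the other end were Grhpr (-0.842), the cytochrome Cyp2e1 (-0.835), Paip2b (-0.814), the carboxylesterase Ces1d (-0.798), Amy1 (-0.796), Nrbp2 (-0.780), Uck2 (-0.779), Aldh6a1 (-0.765), angiotensinogen (Agt, -0.754) and the peroxisomal enzyme Phyh (-0.753), with r from -0.847 to -0.656 and from -0.891 to -0.796 in the clusters. In limma 5586 genes passed an adjusted p of 0.05, with 2580 rising and 3006 falling, against at most 4 in 100 permutations. Within the clusters 2939 genes passed in both with the same sign and 137 with opposite signs. One member of the macrophage list, Ctss, did not follow the rest (partial r -0.01, adjusted p 0.88).

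Of the other 25 lists, 20 passed with the macrophage list. Extracellular matrix had r of 0.741 over all mice, with 0.646 and 0.778 in mice with high and low Y-linked transcripts and 0.610 and 0.782 in the first and second array batch. MHC class II (0.469 and 0.790 in the clusters), cell cycle (0.752 and 0.628), B cell (0.617 and 0.466), T cell (0.524 and 0.472), immediate early (0.502 and 0.449) and interferon response genes (0.217 and 0.226) rose in both clusters. Respiratory chain (-0.486 and -0.604), fatty acid oxidation (-0.470 and -0.590), adipocyte (-0.546 and -0.500), endothelium (-0.453 and -0.494) and lipogenesis genes (-0.583 and -0.371) fell in both. List means of circadian clock (-0.348 and -0.338), exocrine pancreas (-0.334 and -0.259) and mesothelium genes (-0.191 and -0.246) fell in both as well, but not all members did. Of the 13 clock genes 5 fell, 2 rose and 6 did not pass over all mice. Of the 4 exocrine pancreas genes 1 fell and 3 did not pass, and of the 6 mesothelium genes 3 fell and 3 did not pass. For extracellular matrix rho was 0.558 and 0.772, and for the respiratory chain -0.522 and -0.676, all with permutation p of 1e-05. Without the 2 mice farthest from the median of the macrophage list, r was 0.588 and 0.770 for extracellular matrix and -0.463 and -0.596 for the respiratory chain. Within the first and second array batches r was 0.596 and 0.696 for MHC class II, 0.754 and 0.630 for cell cycle, -0.641 and -0.457 for the respiratory chain, -0.567 and -0.443 for fatty acid oxidation, and -0.625 and -0.404 for adipocyte genes. Brown adipocyte genes fell where Y-linked transcripts were low (-0.506) and not detectably where they were high (-0.0141, adjusted p 0.897). Blnk, a member of the B cell list, was itself among the genes closest to the macrophage list. Of the 8 B cell genes 5 rose over all mice and 3 did not pass. The r of the B cell list without Blnk was not computed. Skeletal muscle, mammary epithelium, epididymis and seminal vesicle, and the parental strain alleles passed over all mice with r of -0.127, -0.195, -0.244 and 0.20, and in 1 cluster each (-0.217, -0.330, -0.246 and 0.239, all among mice with high Y-linked transcripts). For epididymis and seminal vesicle genes rho in that cluster was -0.0992 (p 0.224). In the first array batch interferon response (r 0.169, adjusted p 0.0502), skeletal muscle genes (-0.0989, adjusted p 0.259) and the parental strain alleles (0.141, adjusted p 0.0986) did not pass. With array batch as a further covariate, 18 lists passed, and mammary epithelium (r -0.083, adjusted p 0.186) and epididymis and seminal vesicle genes (-0.100, adjusted p 0.114) no longer did. In the first and second array batch the former had r of -0.0326 and -0.138, and the latter 0.000473 and -0.178. Chaperone, red blood cell and liver genes did not pass (-0.0962, 0.0331 and 0.0065). The expansion list was at 0.0053 over all mice, with -0.450 and 0.346 in the clusters, and cholesterol synthesis at 0.0788, with -0.210 and 0.290.

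Some transcripts fell into separate classes of mice rather than a continuous range. After Eif2s3y, with classes 13.4 SD apart, the widest gaps between classes that each held at least 10 percent of mice were in the epididymal Ces5a (9.94 SD), Sult1e1 (8.95 SD), Spink10 (8.88 SD) and the lens crystallin Crygb (8.47 SD). The sperm protamine Prm2 (6.14 SD) and the ciliary regulator Foxj1 (6.94 SD) were also among them. The classes of Sult1e1 were those of the Y-linked transcripts, with all 152 mice with high Y-linked transcripts in its upper class and all 143 others in its lower class. For Foxj1, 129 of the 139 mice in the upper class had high Y-linked transcripts. The upper classes of Ces5a (34 mice), Spink10 (33 mice) and Crygb (48 mice) held only mice with high Y-linked transcripts, of which 28, 27 and 36 were in the second array batch. Ces5a, Spink10, Crygb and Prm2 were not clustered in the first batch alone. Mixtures of normal distributions called 441 genes clustered, 251 with 2 classes and 190 with 3 classes. Of the 441, 261 were also clustered without the 28 arrays of outlying SD, 285 in the first array batch alone, 247 in the second alone and 109 in both. Of the 190, 189 had an outer class of under 10 percent of mice, with medians of 2, 289 and 3 mice in the lower, middle and upper class. The 12 genes with the widest separation by the rule fixed in advance were all of this kind: Fzd8, Fmo5, CLDN3, Pfkfb2, Olfr281, Ina, Prph, Apba3, Sh3pxd2a, Uxs1, Gdf11 and Cx3cr1. Fzd8, at 38.6 SD, had 1 mouse in each outer class and 293 in the middle. With each class required to hold 10 percent of mice, a setting chosen after this was seen, 252 genes were clustered, 232 of them also without the arrays of outlying SD and 144 also with the index taken out.

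**Figure D3:**
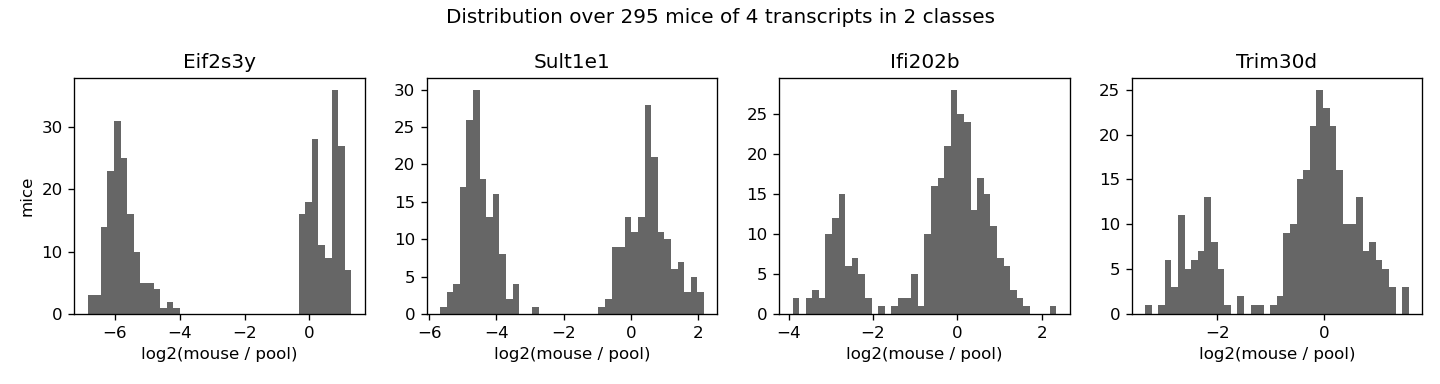
Histograms give the number of mice (vertical axis) at each log2 ratio of mouse over pool (horizontal axis) for Eif2s3y, Sult1e1, Ifi202b and Trim30d in 295 mice. All 4 transcripts form 2 classes, of which the upper holds 51.5% of mice for Eif2s3y and for Sult1e1, 76.9% for Ifi202b and 76.2% for Trim30d.

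Genes that lie near each other on a chromosome are inherited together in an F2, so clustered neighbours were set against clustered genes on different chromosomes. Among 395 autosomal clustered genes, 1404 pairs under 20 Mb apart had a median absolute r of 0.0821 and 73152 pairs on different chromosomes 0.0831. Near pairs were not closer than permuted positions give (one-sided p 0.611, 10000 permutations). With dim and incomplete probes left out the medians were 0.126 and 0.108 (p 0.0261), and without 28 arrays of outlying SD 0.186 and 0.164 (p 0.0337). Of the 395 genes, 230 had classes that each held at least 10 percent of mice. For these the medians were 0.170 and 0.149 (p 0.0715 by the same kind of permutation). The others had a class of fewer mice, so the test over all 395 could hardly show linkage.

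Markers of neighbouring tissues rose steeply in a minority of mice. Genes of epididymis and seminal vesicle were at least 4-fold above the median mouse in 27 mice, all with high Y-linked transcripts, 5 in the first array batch and 22 in the second. Skeletal muscle genes were in 16 mice and brown adipocyte genes in 15, the latter all in the second batch. Exocrine pancreas genes passed in 2 mice and liver genes in 1. None of the 295 mice passed for mammary epithelium, B cell, mesothelium or red blood cell genes. The highest mouse stood at a log2 value of 6.62 above the median for epididymis and seminal vesicle, 4.35 for brown adipocyte and 3.30 for skeletal muscle. With the sign of every ratio turned, 1 mouse passed, for exocrine pancreas.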

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

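Array batch, no loess, occupied classes, shares near 3 to 1 and the turned sign were chosen only after the data were seen, and the other alternatives before. No paired analysis was possible because the labels give 1 group. For results that answer a comparison, 110 alternative values kept their direction and side of the threshold or stayed within 1.5 times the count, 18 moved and 4 reversed. For single genes and lists 2468 were the same, 91 moved, 55 newly passed, 105 no longer passed and 20 reversed. The share rising among genes associated with Lep was 49.9%, and 47.7% with arrays centred, 55.3% with no loess, 53.9% in the value table, 53.8% with ranks and 57.6% in the second array batch, so which direction was more frequent turned. Signal over background was not computed, so no limit by it is given.

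Variable genes numbered 2760 between the 10th and 90th percentile, a narrower span by construction. Genes associated with Lep numbered 3429 in the first array batch of 157 mice, which held 24 of the 28 arrays of outlying SD, and 4104 in the second of 138 mice. Lists associated with Lep numbered 14 and 16 in the index clusters with high and low Y-linked transcripts, 12 with a spline of mouse number and 12 with ranks. Clustered genes numbered 852 in the value table, 239 among complete and brighter probes, 739 in the second array batch, 280 with components at least 4 SD apart and 252 with occupied classes. In the linkage of clustered genes, near pairs had a median absolute r of 0.126 with complete and brighter probes (0.108 on different chromosomes), 0.186 with arrays of outlying SD left out (0.164), 0.325 for shares near 3 to 1 (0.0614) and 0.795 for these with no other tissue (0.0521), these 4 being closer than permuted positions gave. It was 0.0910 with no loess, 0.171 in the second array batch and 0.170 for occupied classes, against 0.0880, 0.165 and 0.149 on different chromosomes, and these 3 were not closer than permuted positions gave (p 0.246, 0.138 and 0.0715). Mice with other tissue markers numbered 19 in the first array batch, 35 in the second, 144 at 2-fold and 1 with the sign turned. Other thresholds and fewer probes change counts by construction. For the other moves, those between array batches included, the cause was not tested.

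Reversals for lists with Lep were, where Y-linked transcripts were low, adipocyte (-0.111), lipogenesis (-0.240), fatty acid oxidation (-0.226), B cell (0.261), immediate early (0.186) and exocrine pancreas (-0.0267). Where they were high these were respiratory chain (0.219), macrophage (-0.295), cell cycle (-0.190), epididymis and seminal vesicle (-0.217) and mammary epithelium (-0.0219). Fatty acid oxidation also reversed in the second array batch (-0.207). With the macrophage list, expansion reversed where Y-linked transcripts were high (-0.450), with ranks (-0.136) and in the first array batch (-0.206), as did cholesterol synthesis where they were high (-0.210), epididymis and seminal vesicle in the first array batch (0.000473) and liver with complete and brighter probes (-0.187). Co-expression reversed for exocrine pancreas where Y-linked transcripts were high (-0.0183) and for liver with complete and brighter probes (-0.00272). The cause was not tested.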

Other observations

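Chosen only after the result was seen were the interaction of Lep with the index, the use of adjusted p within its clusters against chance, the tests of array batch and of RNA of another tissue for the genes near 3 to 1, of array error for the epididymal transcripts, and every use of occupied classes and of shares near 3 to 1.

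Among autosomal genes with 2 classes, 31 divided the mice near 3 to 1, the smaller class holding 20 to 30 percent, and stayed clustered with the index taken out. In 18 of them the upper class was the larger. These included the guanylate-binding protein Gbp2b (upper class 74.9% of mice), the growth factor Hbegf (75.2%), the interferon-inducible Ifi202b (76.9%), Trim30d (76.2%), xanthine dehydrogenase (Xdh, 78.2%), Pttg1 (71.9%), the transcription factor Prdm16 (78.3%) and the ribosomal protein Rps3 (74.6%). In the other 13 the lower class was the larger, as for the muscle genes Atp2a1 (upper class 27.6%) and Tnnt3 (22.5%).

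Brown adipocyte genes were at least 4-fold above the median in 15 mice, 14 of them with low Y-linked transcripts. Skeletal muscle genes were in 16 mice, 12 with low Y-linked transcripts and 5 with an array of outlying SD. These are counts of mice and were not tested.

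A first pattern is the opposite sign of the correlation of Lep with the macrophage list in the clusters of the index, a gap in r of 0.619. Array batch is argued against by the gap within batches, of which the smaller was 0.723 (r -0.506 and 0.217 in the first batch). Leaving out arrays of outlying SD gave a gap of 0.744, and taking out the epididymis and seminal vesicle list one of 0.769. By permutation of the mice, the larger p of the macrophage list within the clusters was 0.000854 after adjustment over all 26 lists. That adjustment covers the choice among the lists. The pattern was chosen with these values in view, however, so they are no separate test of chance. The interaction of Lep with the index was tested because the opposite signs had been seen and is no separate evidence either. The labels give no group, so no biological explanation was tested, and a difference between the sexes, which the labels do not assign, may underlie the pattern only as a hypothesis.

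A second pattern is the 31 genes near 3 to 1. They were picked by their shares from the 144 genes with occupied classes that stayed clustered with the index taken out. How many of the 144 would have such shares without any allele at work was not computed. The count is thus no sign of an excess near 3 to 1. For the 31 genes, an allele of large effect at or near the gene is a hypothesis that the files hold no genotype to test. Array batch is argued against by 28 and 27 of them being clustered in the first and second batch alone, arrays of outlying SD by 30 staying clustered without those arrays, and a trend shared by whole arrays by the correlation of 9 near pairs (median absolute r 0.325 against 0.0614 on different chromosomes, p 0.0002). RNA of another tissue remains undecided for the 31 as a set, since 10 followed a list of another tissue with an absolute r above 0.5, among them 3 members of fixed lists. All 10 were among the 13 genes whose lower class was the larger, but that division was made once this was known, so it is no test. Without the 10, 4 near pairs remained, Rps3 with Trim30d (0.899), Cdsn with H2-Q7 (0.861), Aqr with Slc24a5 (0.729) and Fhod3 with Hbegf (0.224), and probes that bind related transcripts were not tested.

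The last pattern is the 27 mice with epididymis and seminal vesicle genes at least 4-fold above the median. Array error was weighed by arrays of outlying SD, which 2 of these mice had. The second batch held only 4 of the 28 such arrays, so this test could hardly have found array error. Array batch was not weighed, although 22 of the 27 mice lay in the second. RNA of a neighbouring male organ may be the source, as 0 of the 27 mice lay in the cluster with low Y-linked transcripts, in a test that 3 such mice would have turned. Any source limited to mice with high Y-linked transcripts would give the same count. The test therefore cannot tell a neighbouring organ from expression within the fat of these mice. No biological explanation was tested.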
